A study of Mus musculus with 9 samples.

How the data were processed

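Frozen livers of male mice were minced, fixed and dissociated per the labels, and the cells were profiled with the 10x Genomics fixed RNA assay for single samples and the mouse transcriptome probe set. The authors counted the reads with Cell Ranger 7.1.0 against mm10, and the deposited matrices hold raw UMI counts for 19059 genes in the barcodes called as cells. Of the gene IDs, 19048 were found in GENCODE vM21, from which coordinates were taken, and 6 symbols were used more than once, so genes were joined by ID. The 9 libraries held 48993 barcodes and 571432468 UMIs.

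Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which removed 51 barcodes. Scrublet was run on each library, and 2651 barcodes with a score above 0.15 were removed as doublets. Its automatic thresholds called under 0.5% doublets in 5 libraries, and the single threshold was chosen after these values were seen. The 46291 cells kept were 17818 in control, 17307 in fibrosis and 11166 in regression. Counts were scaled to 10000 per cell and log-transformed. From 3000 variable genes 40 principal components were taken, a graph of 15 neighbours was built, and Leiden clustering at resolution 1 gave 49 clusters (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

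Clusters were named by marker sets of 13 classes fixed before the data were examined, as were the gene lists, tests, comparisons and the alternatives other than those said below to be chosen later. The thresholds of the naming score were set after the clusters were seen. A cluster took the class of highest score other than hepatocyte if that score was at least 0.5, and hepatocyte if no other class reached it. It was left unnamed if a second class also reached 0.5 within 0.25 of the first, if the class score was under 0.5, if under 3 markers were at 20 CPM or more, or if more leading genes were markers of another class. A cluster of few UMIs for its libraries with no own marker among its leading genes was left unnamed too. In this way 48 clusters took 1 of 12 classes, 19 of them hepatocyte-like, and 1 cluster of 33 cells took none and was left out of the class comparisons. Class names end in "-like" because they rest on marker RNA alone.

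Raw UMI counts were summed per library over the cells of a class and over all cells. Hepatocyte-, mesenchymal-, macrophage- and endothelial-like cells were compared, and cholangiocyte-like cells were added after the data were seen. Per library the hepatocyte-like class held 2615 to 3323 cells in control, 1540 to 1773 in fibrosis and 1025 to 1562 in regression, with 42023839 to 64059624 UMIs. The mesenchymal-like class held 478109 to 559040 UMIs per library in control, 1302839 to 1745823 in fibrosis and 1782892 to 4053423 in regression. For the macrophage-like class these ranges were 667805 to 903866, 2072095 to 2916775 and 1903249 to 2451006, and for the endothelial-like class 1190899 to 1710997, 2059978 to 2532112 and 2869503 to 3873469.

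Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr, TMM scaling, a robust quasi-likelihood fit of all 9 libraries with 1 mean per group, two-sided tests, and the Benjamini-Hochberg adjustment over the genes tested, with calls at an adjusted p under 0.05. The SE of a log2 change is its size over the square root of the F statistic. CPM are TMM-scaled. The 3 comparisons were fibrosis with control, regression with fibrosis and regression with control. Per class and comparison the genes named were the 3 largest rises and falls that passed the test with no overlap of libraries, at least 20 CPM in the higher group and a level of at least 0.25 of that in the highest other class, up to 4 members of each list, and 20 genes fixed beforehand. This gave 336 values of 179 genes.

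For genes with no counts in a group, the fold is given as at least the ratio to a floor of 3 counts over that group. For 1 to 3 counts the ratio of summed counts is given with a 95% counting interval.

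The 25 lists cover hepatocyte zonation (pericentral, periportal), acute phase, bile acid synthesis and transport, NRF2, p53, cell cycle, fetal and ductal, cholesterol synthesis, PPAR alpha, male-biased and circadian clock genes in hepatocyte-like cells; matrix, contractile, quiescent stellate, matrix protease and inhibitor, and TGF beta and PDGF genes in mesenchymal-like cells; Kupffer, scar-associated, antigen presentation, cytokine and interferon genes in macrophage-like cells; sinusoidal and capillary genes in endothelial-like cells; and immediate early and heat shock genes in all 4 classes. They were tested with fry, adjusted over the 28 tests of a comparison, and with camera using an estimated correlation between genes. Class shares were compared by exact permutation over all assignments for 3 groups and 20 for pairs, adjusted over classes.

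Genes called in both directions were those called in fibrosis against control and, with the opposite sign, in regression against fibrosis. They were set beside the number from independent calls and beside 20 simulated sets of counts with no group effect, in which the shared fibrosis libraries remain shared.

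The fit was tested on simulated data with 200 genes changed 2- or 4-fold. For fibrosis against control it called 63%, 41.4%, 69.7% and 74.7% of the 2-fold changes in hepatocyte-, mesenchymal-, macrophage- and endothelial-like cells and 91.9%, 93.8%, 93.9% and 95.9% of the 4-fold changes. Of its calls 6.1%, 7.04%, 4.73% and 6.15% were unchanged genes, and with nothing changed it called 0. In the whole-library sum it called 67.3% and 93.8%, and in cholangiocyte-like cells 33.7% and 83.8%.

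The alternatives planned were DESeq2 1.42.0, RLE factors, scaling by library size only, no low-count filter, a fit of only the 2 groups compared, a block for replicate number, predicted doublets kept, a stricter cell filter (2000 UMIs and 1000 genes), genes under 0.25 of the highest class mean left out (for gene counts), resolutions 0.5 and 2 (for gene counts and shares), shares among cells that are not hepatocyte-like, and each library left out in turn. Chosen after seeing the data were that filter and these resolutions for all other results, Scrublet's automatic thresholds, clusters high in hepatocyte RNA (score of at least 0.6) left out, clusters led by Derl3 left out, and only cells of 1000 to 3000 UMIs.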

Results

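Livers of male mice were profiled as fixed single cells with a probe-based assay, in which pairs of probes are ligated on their target RNA inside fixed cells and counted by unique molecular identifiers (UMIs). The 9 libraries fell into 3 groups of 3 libraries: untreated controls, fibrosis after 10 weeks of thioacetamide (TAA), and regression, with 10 weeks of TAA followed by 2 weeks of recovery. TAA is a hepatotoxin that enzymes of pericentral hepatocytes turn into reactive products, and long exposure scars the liver. Total UMIs were 60880003 to 72105207 in the control libraries, 55566579 to 60467968 in the fibrosis libraries and 55474306 to 76308870 in the regression libraries. The labels give 8 weeks as the age of every group and no time of day, so neither age nor hour at collection is known or separable from the groups. Gene levels are given in CPM (edgeR's TMM-scaled unit) as mean ± SD over n = 3 libraries, log2 changes as the fitted value ± SE, and adjusted p as edgeR's quasi-likelihood test with the Benjamini-Hochberg correction. For gene lists, fry's p tests whether the genes of a list move on balance one way, without comparing them with other genes. For every named gene with an adjusted p under 0.05, all 3 libraries of the higher group lay above all 3 of the lower group, except where stated.

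The dissociated cells recovered need not match the tissue. They fell into 12 classes whose shares differed between groups. Hepatocyte-like cells, the parenchyma, were 51.5 ± 4.84% of cells in control (SD, n = 3), 28.8 ± 1.08% in fibrosis and 32.3 ± 4.10% in regression. Cholangiocyte-like cells, which line bile ducts, were 1.63 ± 0.413%, 7.92 ± 3.27% and 4.64 ± 0.601%, and macrophage-like cells 9.05 ± 0.513%, 18.0 ± 2.30% and 13.8 ± 1.35%. Mesenchymal-like cells, which hold the hepatic stellate cells that make scar matrix, were 7.66 ± 0.719%, 10.7 ± 1.31% and 12.9 ± 0.550%. Dendritic-like cells were 0.654 ± 0.242%, 3.75 ± 0.252% and 1.39 ± 0.119%.

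Among the smaller classes, neutrophil-like cells were 0.329 ± 0.149% in control, 1.64 ± 0.951% in fibrosis and 0.714 ± 0.298% in regression, and NK-like cells 0.206 ± 0.144%, 0.948 ± 0.246% and 0.770 ± 0.122%. B-like cells were 1.96 ± 1.2%, 4.84 ± 1.26% and 5.03 ± 0.908%, T-like cells 1.83 ± 0.802%, 4.16 ± 1.16% and 2.89 ± 1.05%, and mesothelial-like cells, of the liver's outer lining, 1.39 ± 0.414%, 0.491 ± 0.042% and 0.996 ± 0.263%. Endothelial-like cells were 23.7 ± 2.99%, 18.6 ± 1.5% and 24.0 ± 1.41%, and erythroid-like cells 0.028 ± 0.027%, 0.030 ± 0.012% and 0.542 ± 0.103%. The 71 erythroid-like cells formed 1 cluster, which was high in hepatocyte RNA (score 0.755).

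By exact permutation over all assignments of the 9 libraries (two-sided, Benjamini-Hochberg over 12 classes), the shares differed among the 3 groups in 11 classes. The adjusted exact p was 0.00857 for the cholangiocyte-, mesenchymal-, macrophage-, dendritic- and neutrophil-like classes, 0.0184 for hepatocyte- and mesothelial-like cells, 0.0214 for NK-like cells and 0.0468 for endothelial- and B-like cells. Erythroid-like cells had adjusted p = 0.0429 and T-like cells 0.0786 in the same exact test. A pairwise exact test of 3 against 3 cannot go below p = 0.10. Control and fibrosis did not overlap in any class (exact p = 0.10) but the erythroid-like one (exact p = 0.90), while regression and fibrosis overlapped for hepatocyte-like (0.30), T-like (0.30), NK-like (0.40) and B-like cells (0.90, all exact). The number of classes that differed was 7 without fibrosis library 1 (endothelial- and B-like cells were among those lost) and 6 without fibrosis library 2. Shares of 1 class move those of all others: among cells that were not hepatocyte-like, 7 classes differed, and mesenchymal-, macrophage- and B-like cells were not among them (adjusted p = 0.0786, 0.0688 and 0.0864, exact permutation).

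The libraries also differed in how deeply cells were read. The median UMIs per barcode were 1659 to 2764 in control, 2095 to 2612 in fibrosis and 3105 to 4072.5 in regression. The lowest UMIs of any barcode was 497 to 499 in the first 6 libraries but 870, 588 and 583 in the regression libraries, so cells with few UMIs enter the shares unequally. RNA of hepatocytes reached the other classes too. The level of Alb, the gene of serum albumin, in mesenchymal-like cells was 31.1 ± 8.89% of that in hepatocyte-like cells in control, 26.3 ± 7.90% in fibrosis and 61.1 ± 14.4% in regression (SD, n = 3). In macrophage-like cells it was 22.6 ± 1.90%, 19.9 ± 1.54% and 43.3 ± 3.61%, and in endothelial-like cells 26.1 ± 2.19%, 22.6 ± 3.85% and 33.7 ± 6.03%. T-like cells, which do not make albumin, were at 31.3 ± 3.92%, 25.8 ± 4.67% and 31.6 ± 10.5%.

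**Figure D1:**
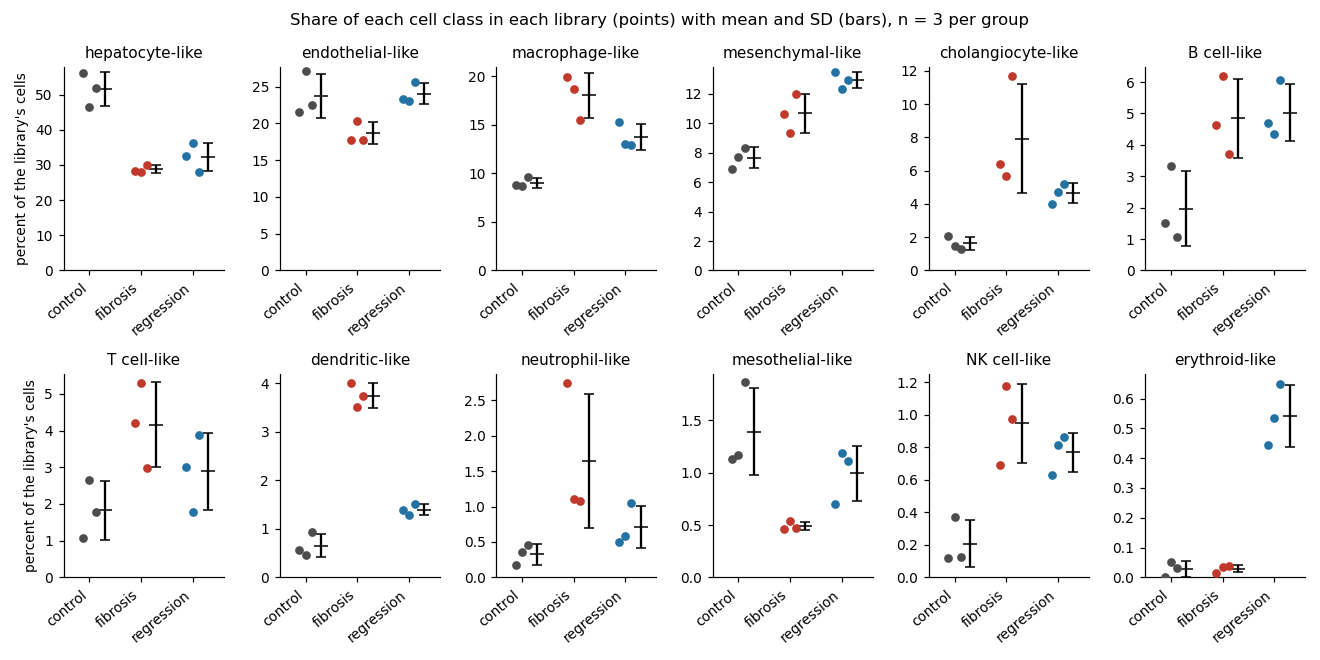
Each panel plots the percent of a library's cells that fell into a class, with points for the 3 libraries of each group and a bar for mean and SD. Hepatocyte-like cells took 51.5% of control cells against 28.8% in fibrosis.

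The comparison of fibrosis with control asks what 10 weeks of TAA left changed. In hepatocyte-like cells, genes of the zone around the central vein were lower: Glul, which makes glutamine from ammonia, fell from 166 ± 21.8 to 11.5 ± 5.19 CPM (log2 change −3.86 ± 0.33, adjusted p = 2.76e-05). The glutamate transporter gene Slc1a2 fell 265-fold, from 131 ± 17.6 to 0.492 ± 0.187 CPM (−8.05 ± 0.25, adjusted p = 4.46e-08), and Cyp2e1, a cytochrome P450 that oxidises TAA, from 1990 ± 657 to 419 ± 208 CPM (−2.25 ± 0.40, adjusted p = 0.00157). Of 16 pericentral genes tested, 10 fell and 2 rose, Axin2 among them (1.79 ± 0.43), with the same counts adjusted over the list alone. The list moved down on balance by fry (adjusted p = 0.00229, but adjusted p = 0.209 with an estimated correlation). Of 14 periportal genes, 5 fell and 1 rose, also over the list alone (fry adjusted p = 0.00229, adjusted p = 0.249 with an estimated correlation). Pigr, which carries IgA into bile, fell from 1990 ± 253 to 507 ± 63.3 CPM, and Pck1, of glucose synthesis, from 4400 ± 218 to 1830 ± 498 CPM (−1.26 ± 0.23, and −0.83 when scaled by library size). The periportal list was no longer called when scaled by library size, where its direction turned (adjusted p = 0.463), or without hepatocyte-like clusters led by Derl3 (0.484).

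Further metabolic genes of hepatocytes fell with them. Of 15 genes of bile acid synthesis and transport, 9 fell and 2 rose (10 and 2 adjusted over the list alone, fry adjusted p = 0.00945, adjusted p = 0.337 with an estimated correlation). The call ended with library size scaling (adjusted p = 0.118). The oxysterol hydroxylase Cyp7b1 fell from 289 ± 72.5 to 22.6 ± 4.36 CPM, while the export pump Abcc4 rose from 0.579 ± 0.125 to 26.9 ± 7.02 CPM (5.53 ± 0.31). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 176 ± 62.3 and 141 ± 30.4 CPM (−0.31 ± 0.38, adjusted p = 0.532, and 0.11 with library size scaling). Of 9 genes that are higher in male than in female livers, 7 fell, also over the list alone (fry adjusted p = 0.000366, adjusted p = 0.0762 with an estimated correlation). The steroid dehydrogenase Hsd3b5 fell 214-fold, from 57.3 ± 25.0 to 0.266 ± 0.154 CPM, and the transporter Slco1a1 by 101-fold, from 117 ± 43.1 to 1.16 ± 0.769 CPM. Susd4, a regulator of complement, fell 177-fold to 0.174 ± 0.0831 CPM. Of 15 acute phase genes 11 fell (12 over the list alone), among them the fibrinogen gene Fga (−1.46 ± 0.21), but the list did not pass (fry adjusted p = 0.0625). It passed without control library 2 or 3 (lowest adjusted p = 0.0223).

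Stress, damage and growth genes moved up in hepatocyte-like cells. All but 1 of 14 targets of NRF2, the regulator of the response to oxidants, rose, also over the list alone (fry adjusted p = 7.14e-05, adjusted p = 0.0505 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose from 14.6 ± 0.862 to 61.3 ± 6.05 CPM (2.07 ± 0.11, adjusted p = 1.19e-06). The cystine carrier Slc7a11 had 2 UMIs in all control libraries and 13.0 ± 1.82 CPM in fibrosis, a ratio of 1030 (95% counting interval 285 to 8500). Of 13 p53 targets 9 rose, also over the list alone (fry adjusted p = 8.38e-05, adjusted p = 0.0762 with an estimated correlation). Among them were the cell cycle inhibitor Cdkn1a (1.78 ± 0.37, from 43.6 ± 14.7 to 149 ± 19.1 CPM) and Phlda3 (5.57 ± 0.20, from 0.597 ± 0.158 to 28.5 ± 2.67 CPM). All 20 cell cycle genes rose, also over the list alone (fry adjusted p = 0.000191, adjusted p = 0.0762 with an estimated correlation). The mitotic kinase gene Plk1 rose from 0.731 ± 0.295 to 10.5 ± 0.542 CPM and Mki67, a marker of cycling cells, from 0.653 ± 0.670 to 23.1 ± 1.30 CPM. Of 12 fetal and ductal genes, 9 rose (10 over the list alone, fry adjusted p = 0.000191, adjusted p = 0.0762 with an estimated correlation).

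Afp, the fetal counterpart of albumin, rose 161-fold in hepatocyte-like cells, from 0.217 ± 0.0904 to 35.1 ± 9.65 CPM (7.33 ± 0.38, adjusted p = 1.31e-06). Cd63, a membrane protein of lysosomes, rose 93.1-fold, from 2.13 ± 0.288 to 199 ± 38.5 CPM. Sprr1a, a cornified envelope protein that injured cells also make, had 1 UMI in all control libraries and 34.2 ± 39.6 CPM in fibrosis, a ratio of 5360 (961 to 212000). Fibrosis library 1 held most of it (79.9 CPM, against 10.1 and 12.6), and without that library the log2 change was 10.33 in place of 11.93. Sox9, of ductal cells, was at 18.6 ± 9.23 and 16.2 ± 0.984 CPM (−0.20 ± 0.31, adjusted p = 0.633). Without control library 3 it was at 0.19, with library size scaling at 0.27, and without control library 2 it fell by 0.52 (adjusted p = 0.0353). Several of the named genes are far higher in another class: in hepatocyte-like cells Phlda3 lay at 9.9% of its highest level elsewhere, Mki67 at 11.8% and Plk1 at 21.7%.

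Mesenchymal-like cells of fibrotic livers carried more matrix RNA. Col1a1, the main chain of scar collagen, rose 10-fold, from 779 ± 102 to 7810 ± 5320 CPM (3.33 ± 0.43, adjusted p = 0.000264). The matrix protein gene Thbs1 rose from 41.7 ± 12.2 to 208 ± 59.6 CPM, the plasminogen activator Plat from 14.3 ± 7.1 to 165 ± 43.2 CPM (3.55 ± 0.31), and Timp3, an inhibitor of matrix proteases, from 66.4 ± 25.9 to 479 ± 126 CPM (2.86 ± 0.29). Of 25 matrix genes 16 rose and 1 fell (19 and 1 over the list alone, fry adjusted p = 0.00322, adjusted p = 0.0762 with an estimated correlation). Of 13 proteases and inhibitors 7 rose (9 over the list alone, fry adjusted p = 0.00102, adjusted p = 0.0505 with an estimated correlation). Of 16 genes of TGF beta and PDGF signalling, 6 rose and 1 fell (7 and 1 over the list alone, fry adjusted p = 0.00322, adjusted p = 0.0762 with an estimated correlation). This call ended with the stricter cell filter. Ltbp2, which binds fibrillin, rose 32.8-fold to 282 ± 127 CPM, and the ligand Tgfb3 from 18.3 ± 12.3 to 72.9 ± 10.7 CPM, while the activin chain Inhba fell by 1.08 (SE 0.24).

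Contractile genes of these mesenchymal-like cells rose in 3 of 9 cases, and 6 rose and 1 fell over the list alone (fry adjusted p = 0.0265, adjusted p = 0.224 with an estimated correlation). This call ended without control library 2, fibrosis library 1 or 3, the low-count filter or clusters high in hepatocyte RNA, in the fit of only these groups, with Scrublet's automatic thresholds and in cells of 1000 to 3000 UMIs. The tropomyosin gene Tpm1 rose from 419 ± 108 to 1050 ± 272 CPM (1.32 ± 0.26). Acta2, the smooth muscle actin of activated stellate cells, was at 12 ± 9.09 and 136 ± 84.2 CPM (3.55 ± 0.88, adjusted p = 0.0448). Its call was kept in 9 of 20 other settings and ended without control library 1, 2 or 3 or fibrosis library 3. Timp1, another protease inhibitor, was at 3.02 ± 2.66 and 36.1 ± 31.0 CPM (3.55 ± 0.84, adjusted p = 0.0171), but its call ended without control library 1, 2 or 3. Of 15 genes of quiescent stellate cells 6 fell, 8 over the list alone (fry adjusted p = 0.0205, adjusted p = 0.211 with an estimated correlation). The list's call ended without control library 2, fibrosis library 1 or fibrosis library 3, with library size scaling (0.104), with predicted doublets kept and with the stricter cell filter, and its direction turned in 1 setting. Vipr1, a receptor for vasoactive intestinal peptide, fell from 958 ± 297 to 223 ± 103 CPM and Angptl6 from 1160 ± 81.0 to 288 ± 134 CPM. Lrat, which stores retinol as esters, was at 528 ± 113 and 622 ± 194 CPM (0.23 ± 0.28, adjusted p = 0.690).

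The genes with the largest rises among mesenchymal-like cells were Casq2, a calcium-binding protein of muscle (no UMI in control, 22.8 ± 8.77 CPM in fibrosis, at least 13-fold higher against 3 UMIs over the group), the fibrillin gene Fbn2 and the mitotic gene Knstrn. Fbn2 was at a log2 change of 6.53 ± 0.68 (1.36 ± 2.35 to 119 ± 57.3 CPM, a ratio of 102 with a counting interval of 28.1 to 842, and 10.59 without control library 1, which held its control UMIs). Knstrn went from 0.599 ± 1.04 to 26.8 ± 6.50 CPM (a ratio of 43.3 from 1 UMI in control, 7.64 to 1720, and a fitted log2 change of 5.28, or 8.44 without control library 2). The largest falls were those of hepatocyte genes, whose level there was 36.7% to 49% of that in hepatocyte-like cells. They were Slco1a1 (−5.14 ± 0.72, but 3.29 with the stricter cell filter, adjusted p = 0.921), the fatty acid elongase Elovl3 (−4.31 ± 0.72) and the major urinary protein gene Mup12 (−5.99 ± 1.22, adjusted p = 0.0222, which ended without fibrosis library 1, 2 or 3). Immediate early and heat shock genes moved down on balance among mesenchymal-like cells (0 rose and 2 of 16 fell, 6 over the list alone, fry adjusted p = 0.00397, adjusted p = 0.117 with an estimated correlation). Zfp36, which destabilises mRNA, fell from 419 ± 47.7 to 144 ± 63.8 CPM. Scaled by library size this list was not called (adjusted p = 0.0795), nor with predicted doublets kept or the stricter cell filter. That filter, which left 1 control library here, also ended most calls of single mesenchymal genes, that of Col1a1 among them (adjusted p = 0.0806).

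Macrophage-like cells gained the genes of scar-associated macrophages. Gpnmb, a glycoprotein of lipid-laden macrophages, had 3 UMIs in the control libraries and 1060 ± 398 CPM in fibrosis, a ratio of 873 (95% counting interval 298 to 4230, adjusted p = 2.7e-09). The lipid receptor gene Trem2 rose from 33.8 ± 2.97 to 254 ± 39.8 CPM (2.91 ± 0.19, adjusted p = 3.49e-08) and Cd63 from 14.4 ± 4.49 to 318 ± 81.5 CPM (4.51 ± 0.27). Of 17 genes of monocyte-derived and scar-associated macrophages 11 rose and none fell (15 and 0 over the list alone, fry adjusted p = 0.00102, adjusted p = 0.0505 with an estimated correlation). Spp1, osteopontin, was at 4.79 ± 8.30 and 60.5 ± 42.4 CPM and did not pass (3.39 ± 1.14, adjusted p = 0.118), and in macrophage-like cells it lay at 0.7% of its highest level elsewhere. Atp6v0d2, a subunit of the proton pump of lysosomes, had no UMI in control and 32.2 ± 12.2 CPM in fibrosis, at least 26.3-fold higher against 3 UMIs over the group (adjusted p = 0.0991 with the stricter cell filter). Syngr1 had 1 UMI in control and 37.8 ± 12.4 CPM in fibrosis, a ratio of 91.7 (16.3 to 3640).

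Genes of Kupffer cells, the resident macrophages, fell in 6 of 13 cases, 8 over the list alone (fry adjusted p = 0.0196, adjusted p = 0.200 with an estimated correlation). That call ended without control library 1, control library 2 or fibrosis library 3 and in the fit of only these groups. The haemoglobin scavenger receptor Cd163 fell from 3020 ± 668 to 883 ± 319 CPM (−1.78 ± 0.26, adjusted p = 0.000431). The lectin gene Clec4f was at 6380 ± 776 and 3350 ± 1220 CPM (−0.93 ± 0.24, adjusted p = 0.0179, which ended without control library 2 or fibrosis library 1 or 3 and with the stricter cell filter, 0.057). Timd4, a receptor for dying cells, was at 547 ± 67.4 and 221 ± 114 CPM (−1.30 ± 0.32, adjusted p = 0.0246, which was kept in 13 of 20 other settings and ended without control library 1, 2 or 3 or fibrosis library 3 and with the stricter cell filter, 0.112). The largest falls were of the hepatocyte genes Mup12, Elovl3 and Mup17, which lay at 28.7%, 30.7% and 53.6% of their level in hepatocyte-like cells. Mup12 fell by 5.85 (SE 0.97, adjusted p = 0.0099, or 0.0646 without fibrosis library 1). Immediate early genes went both ways in macrophage-like cells (3 of 18 rose and 3 fell, or 3 and 5 over the list alone, fry adjusted p = 0.322), with a median of 0.01 against a mean of −0.21. Jun rose by 1.22 ± 0.19 and Fos fell by 1.22 (SE 0.24, or 0.76 and not called with the stricter cell filter, adjusted p = 0.328).

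Endothelial-like cells took on genes of capillaries and larger vessels. Cd34 rose from 13.4 ± 1.30 to 83.7 ± 6.05 CPM (2.65 ± 0.20, adjusted p = 2.57e-07) and the endothelin receptor Ednrb from 14.1 ± 6.88 to 308 ± 101 CPM (4.51 ± 0.46, adjusted p = 0.000542). Ly6a rose from 63.3 ± 9.86 to 300 ± 43.4 CPM and Plvap, of the diaphragms of fenestrae, from 149 ± 41.9 to 263 ± 45.0 CPM (0.83 ± 0.17). Of 15 capillary and vascular genes 5 rose and 1 fell (6 and 1 over the list alone, fry adjusted p = 0.00212, adjusted p = 0.0762 with an estimated correlation). Of 18 genes of sinusoidal endothelium 5 fell and 1 rose (9 and 1 over the list alone), which did not pass (fry adjusted p = 0.0708). Ehd3, of endosomes, fell from 2760 ± 57.4 to 1570 ± 337 CPM, and the hyaluronan scavenger Stab2 from 4130 ± 478 to 2700 ± 146 CPM (−0.61 ± 0.15, adjusted p = 0.011, or 0.0534 without control library 2). Of 17 immediate early genes 1 rose, also over the list alone, and the list did not pass (fry adjusted p = 0.103). Wnt9b, a Wnt ligand of the central vein, rose from 53.8 ± 10.8 to 141 ± 44.5 CPM, and Lyve1 was at 501 ± 73.0 and 621 ± 56.0 CPM (0.31 ± 0.15, adjusted p = 0.196). The hepatocyte genes Elovl3 (26.9% of its level in hepatocyte-like cells), Mup12 (31.1%) and Mup17 (52.5%) fell by 4.41, 5.33 and 3.83. Mup12 did not pass without fibrosis library 1, 2 or 3. The glutathione transferase gene Gstm3, at 25.2% of its hepatocyte level, rose by 4.59 ± 0.43.

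By edgeR, 3154 genes rose and 2529 fell of 12756 tested in hepatocyte-like cells, 546 and 421 of 11139 in mesenchymal-like, 625 and 556 of 10836 in macrophage-like, and 832 and 637 of 10943 in endothelial-like cells. Of the 28 list tests 17 passed by fry but 0 by camera with an estimated correlation (11 at an unadjusted p under 0.05). Scaled by library size alone the hepatocyte split was 6595 to 597, with the median gene shifted by 0.445 on the log2 scale, the mesenchymal one 618 to 258 and the endothelial one 1150 to 430. The mesenchymal, macrophage and endothelial counts of 967, 1181 and 1469 were 524, 644 and 816 at the lowest with 1 library left out, 85, 388 and 338 with the stricter cell filter, and 1662, 3194 and 2735 with Scrublet's automatic thresholds. Clusters of a class differed between groups, which cannot tell a change in cell types from a shift within them or a batch. Cluster 0 held 85.9% of control mesenchymal-like cells and cluster 18 held 55.2% of those in fibrosis. Cluster 5 held 82.9% of control macrophage-like cells and cluster 22 held 47.3% in fibrosis. Cluster 3 held 89.1% of control endothelial-like cells and cluster 6 held 73.9% in fibrosis. The largest hepatocyte-like cluster was 2 in control (15.1%) and 40 in fibrosis (42.0%).

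**Figure D2:**
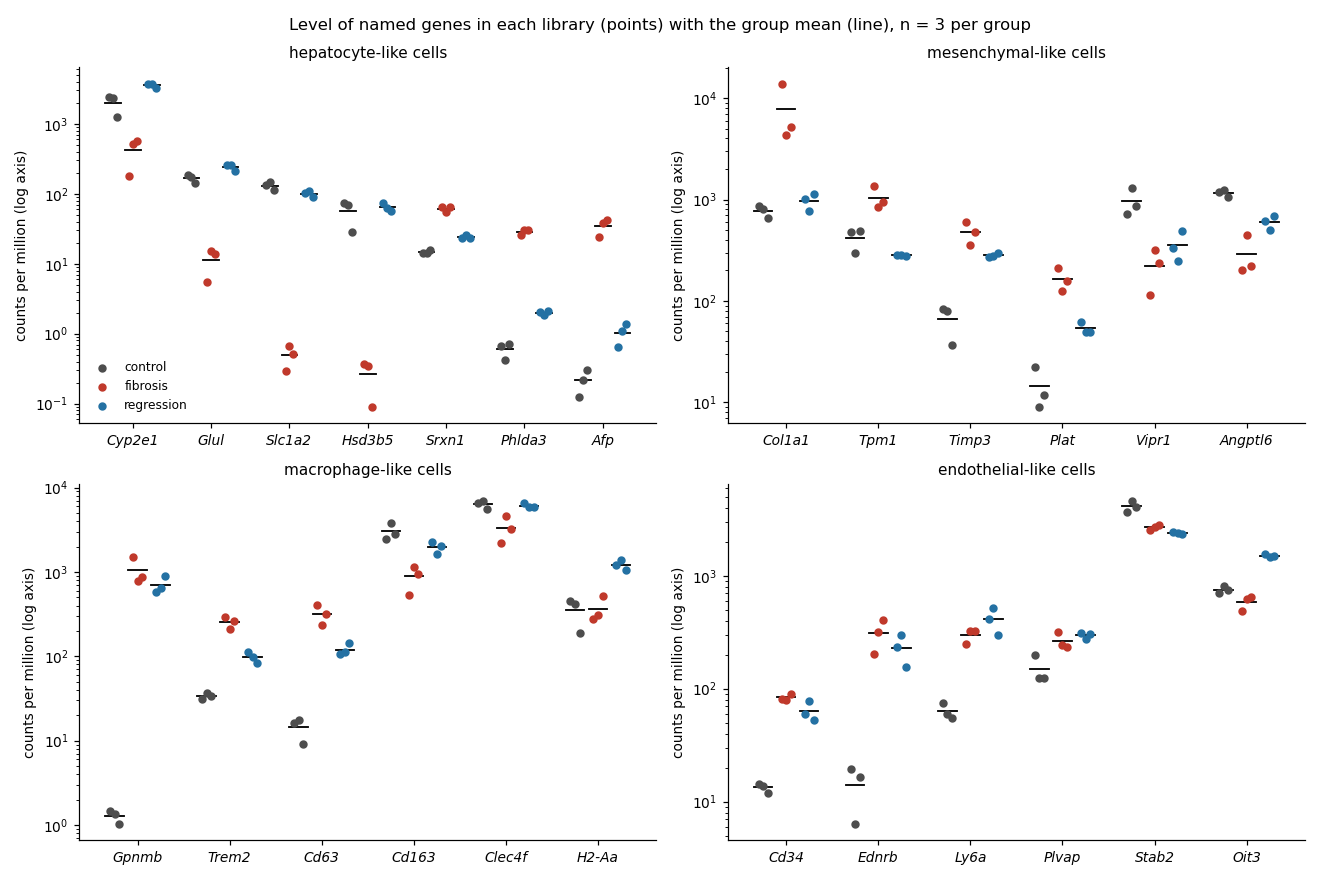
Each point is the level of a gene in 1 library in CPM on a log axis, grouped by class, with 3 libraries per group and a line at the group mean. Cd34 of endothelial-like cells stayed at 63.3 CPM in regression against 13.4 CPM in control.

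The comparison of regression with fibrosis asks what moved during 2 weeks without TAA. In hepatocyte-like cells the pericentral genes came back. Glul rose 21.2-fold, from 11.5 ± 5.19 to 243 ± 24.9 CPM (4.41 ± 0.34, adjusted p = 3.43e-05) and Slc1a2 from 0.492 ± 0.187 to 100 ± 8.92 CPM (7.66 ± 0.25, adjusted p = 1.33e-07). Cyp2e1 rose from 419 ± 208 to 3560 ± 305 CPM (3.08 ± 0.42, adjusted p = 0.000407). Of 16 pericentral genes 11 rose and none fell (11 and 1 over the list alone, fry adjusted p = 0.00127, adjusted p = 0.288 with an estimated correlation). Of 14 periportal genes 5 rose, also over the list alone (fry adjusted p = 0.00127, adjusted p = 0.309 with an estimated correlation). The list's call ended with library size scaling (0.302) and without clusters led by Derl3. Pigr rose from 507 ± 63.3 to 1670 ± 147 CPM. All 9 male-biased genes rose, also over the list alone (fry adjusted p = 0.000157, adjusted p = 0.175 with an estimated correlation), Hsd3b5 from 0.266 ± 0.154 to 64.6 ± 7.82 CPM and the major urinary protein gene Mup3 from 1450 ± 327 to 7870 ± 300 CPM. In the bile acid list, 9 of 15 genes rose and 1 fell (10 and 1 over the list alone, fry adjusted p = 0.00227, adjusted p = 0.309 with an estimated correlation), with Cyp7b1 up 16.4-fold and Slco1a1 up 114-fold.

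Genes of stress and growth came down in hepatocyte-like cells. Of 13 p53 targets 10 fell, also over the list alone (fry adjusted p = 0.000157, adjusted p = 0.175 with an estimated correlation): Phlda3 from 28.5 ± 2.67 to 2 ± 0.128 CPM (−3.83 ± 0.18) and Cdkn1a from 149 ± 19.1 to 44.8 ± 24.0 CPM (−1.74 ± 0.37). Of 14 NRF2 targets 7 fell and 1, Gclm, rose, also over the list alone (fry adjusted p = 0.00262, adjusted p = 0.309 with an estimated correlation). Slc7a11 fell 76.4-fold and Srxn1 from 61.3 ± 6.05 to 24.3 ± 1.28 CPM, while Gclm, of glutathione synthesis, rose by 0.76 ± 0.17 (0.31, not called, with library size scaling). Of 20 cell cycle genes 19 fell, also over the list alone (fry adjusted p = 0.00427, adjusted p = 0.309 with an estimated correlation), with Plk1 down 5.07-fold to 2.07 ± 0.288 CPM. Mki67 was at 5.62 ± 2.6 CPM (−2.04 ± 0.58, adjusted p = 0.0205), which ended without fibrosis library 2 or 3 or regression library 2 or 3. Of 12 fetal and ductal genes 9 fell, also over the list alone (fry adjusted p = 0.00127, adjusted p = 0.288 with an estimated correlation). Afp fell 33.9-fold, to 1.04 ± 0.365 CPM, Cd63 12.2-fold, to 16.3 ± 1.67 CPM, and Sprr1a 92-fold, to 0.366 ± 0.223 CPM (−6.52, or −4.93 without fibrosis library 1). Cyp7a1 was at 138 ± 62.7 CPM in regression (−0.03 ± 0.38, adjusted p = 0.95) and Sox9 at 15.7 ± 2.18 CPM (−0.05 ± 0.32, adjusted p = 0.914). Both signs turned without 1 library.

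In mesenchymal-like cells the matrix genes fell. Col1a1 fell 7.99-fold, from 7810 ± 5320 to 977 ± 190 CPM (−3 ± 0.42, adjusted p = 6.42e-05), the collagen cross-linking enzyme Lox from 94.5 ± 49.2 to 16.5 ± 3.61 CPM (−2.49 ± 0.31), and Col5a2 from 195 ± 74.7 to 57.5 ± 6.51 CPM (−1.76 ± 0.23). Of 25 matrix genes 14 fell and 1 rose, also over the list alone (fry adjusted p = 0.00316, adjusted p = 0.309 with an estimated correlation). Of 13 proteases and inhibitors 9 fell and 1 rose (10 and 1 over the list alone, fry adjusted p = 0.00303, adjusted p = 0.309 with an estimated correlation). Plat fell from 165 ± 43.2 to 53.8 ± 7.53 CPM and Timp1 from 36.1 ± 31.0 to 7.32 ± 0.547 CPM (−2.31 ± 0.51, or −1.31 without fibrosis library 1). Mmp19, a metalloprotease, rose by 0.88 ± 0.23, a value that was −0.09 and not called without the clusters high in hepatocyte RNA. Of 9 contractile genes 6 fell, also over the list alone (fry adjusted p = 0.0113, adjusted p = 0.443 with an estimated correlation), Tpm1 to 281 ± 4.38 CPM (−1.90 ± 0.26). Acta2 was at 41.5 ± 29.6 CPM (−1.66 ± 0.59, adjusted p = 0.0497), with libraries of the groups overlapping. The call was kept in 5 of 20 other settings and ended without fibrosis library 1 (−1.04, adjusted p = 0.0996) or 3 or regression library 1 or 3.

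The TGF beta and PDGF list also fell in mesenchymal-like cells (9 of 16 fell, 10 over the list alone, fry adjusted p = 0.00303, adjusted p = 0.309 with an estimated correlation), Ltbp2 8.02-fold, to 35.1 ± 1.88 CPM, and Tgfb3 2.93-fold, to 25.2 ± 8.06 CPM. Genes of quiescent stellate cells went both ways (2 of 15 rose and 1 fell, 1 and 1 over the list alone, fry adjusted p = 0.576). Angptl6 rose by 1.06 ± 0.29 (adjusted p = 0.00802, or 0.0504 without fibrosis library 3). Lrat fell by 0.93 (SE 0.28, adjusted p = 0.0147). The Lrat call was kept in 13 of 20 other settings and ended without fibrosis library 1 or 2 or regression library 2. For immediate early genes, 4 of 16 rose (3 over the list alone) and the list's median, −0.07, had the other sign than its mean, 0.15, and its test (up, fry adjusted p = 0.0431, adjusted p = 0.673 with an estimated correlation). It turned down with library size scaling (0.0471) and was not called without fibrosis library 1, fibrosis library 3 or any 1 of the regression libraries, in the fit of only these groups, with predicted doublets kept, with automatic thresholds or with the stricter cell filter. The largest falls were those of Ankle1, Ckap2 and Neil3, genes of dividing cells, with Ankle1 at 35.5 ± 14.8 and 0.592 ± 0.110 CPM and Neil3 at −5.17 ± 0.64 (−8.54 without regression library 2). The largest rises were those of the hepatocyte genes Slco1a1, Hsd3b5 and Cyp4a12b, which lay at 49%, 43.6% and 56.3% of their hepatocyte level. Slco1a1 rose from 0.849 ± 1.04 to 97.1 ± 21.9 CPM, Hsd3b5 by a ratio of 232 from 1 UMI in fibrosis (41.3 to 9200) and Cyp4a12b by a ratio of 117 (32.1 to 970).

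Among macrophage-like cells, Kupffer genes rose on balance. Trem2, of the scar-associated list, fell from 254 ± 39.8 to 97.0 ± 14.7 CPM (−1.39 ± 0.15, adjusted p = 2.31e-06) and Cd63 from 318 ± 81.5 to 120 ± 19.7 CPM (−1.41 ± 0.19), but in cells of 1000 to 3000 UMIs Trem2 fell by only 0.88 and Cd63 by 0.68. Gpnmb was at 701 ± 163 CPM (−0.59 ± 0.23, adjusted p = 0.0467), with overlapping libraries, and its call was kept in 9 of 20 other settings and ended without fibrosis library 1 (−0.24, adjusted p = 0.340) or regression library 1 or 2. In those cells the Gpnmb value was 0.16 (adjusted p = 0.580). The scar-associated list did not pass (5 of 17 fell, 4 over the list alone, fry adjusted p = 0.0798), but passed without fibrosis library 2, with library size scaling and with genes under 0.25 of the highest class mean left out. Of 13 Kupffer genes 8 rose (9 over the list alone, fry adjusted p = 0.0114, adjusted p = 0.475 with an estimated correlation), and the call ended with library size scaling (0.076). Clec4f rose from 3350 ± 1220 to 6060 ± 365 CPM (0.85 ± 0.24, or 0.52 and not called with library size scaling), the transcription factor Spic from 49.2 ± 14.8 to 122 ± 25.7 CPM, and Folr2 from 207 ± 73.5 to 526 ± 57.9 CPM. Timd4 was at 480 ± 109 CPM (1.12 ± 0.31, adjusted p = 0.0157, which ended without fibrosis library 3 or regression library 3, with library size scaling, in the fit of only these groups, with the stricter cell filter and in cells of 1000 to 3000 UMIs), and Spp1 at 28.4 ± 13.0 CPM (−1.09 ± 0.71, adjusted p = 0.275).

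The largest rises among macrophage-like cells were again of hepatocyte genes, Slco1a1, Hsd3b5 and Cyp4a12b, at 28.6%, 32.9% and 51% of their hepatocyte level, Slco1a1 by a ratio of 218 from 2 UMIs in fibrosis (59.9 to 1810). The largest falls were of Spag5, a gene of the mitotic spindle (−1.89 ± 0.42), Ankle1 (−1.96 ± 0.63, adjusted p = 0.0359) and Rad51b, of DNA repair (−2.04 ± 0.71, adjusted p = 0.0488). The calls of Ankle1 and Rad51b were kept in 13 and 10 of 20 other settings, and each ended without fibrosis library 1 or 3 or regression library 1 or 2, and without regression library 3 Ankle1 fell by 2.95.

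In endothelial-like cells, sinusoidal genes rose during recovery. Oit3 rose from 585 ± 87.8 to 1490 ± 49.6 CPM (1.35 ± 0.15, adjusted p = 1e-05). The inhibitory Fc receptor Fcgr2b rose from 1130 ± 77.9 to 2390 ± 284 CPM (1.08 ± 0.15) and Lyve1, a receptor for hyaluronan, from 621 ± 56.0 to 957 ± 130 CPM (0.62 ± 0.15). Of 18 sinusoidal genes 11 rose and none fell, also over the list alone (fry adjusted p = 0.00262, adjusted p = 0.309 with an estimated correlation), a call that ended with Scrublet's automatic thresholds (0.114). Stab2 was at 2410 ± 42.5 CPM (−0.17 ± 0.15, adjusted p = 0.402) and Plvap at 298 ± 18.2 CPM (0.18 ± 0.16, adjusted p = 0.423, and −0.02 with library size scaling). Of 15 capillary and vascular genes 4 rose and 3 fell (6 and 3 over the list alone, fry adjusted p = 0.147), and the collagen genes Col4a1 and Col4a2 of the basement membrane fell by 0.71 and 0.86 on the log2 scale. Cd34 was at 63.3 ± 12.9 CPM (−0.40 ± 0.15, adjusted p = 0.0489), but at 0.03 in cells of 1000 to 3000 UMIs (adjusted p = 0.948). This call was kept in 5 of 20 other settings and ended without any 1 library but regression library 2.

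Immediate early genes of endothelial-like cells moved up on balance (4 of 17 rose and 1 fell, also over the list alone, fry adjusted p = 0.0473, adjusted p = 0.486 with an estimated correlation). The list's call was kept in 7 of 20 other settings, and ended without fibrosis library 2 or 3 or any 1 of the regression libraries and with library size scaling (0.688). The flow-responsive factor Klf2 rose from 570 ± 90.3 to 949 ± 64.2 CPM. The largest falls were those of Stx1a, a syntaxin (−2 ± 0.18), Cdh24 and Armcx4. The largest rises were those of Hsd3b5 (a ratio of 51.3 from 3 UMIs in fibrosis, 17.3 to 251), Elovl3 and Mup17, hepatocyte genes at 28.5%, 26.9% and 52.5% of their hepatocyte level.

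By edgeR, 2504 genes rose and 3550 fell in hepatocyte-like cells, 2390 and 2444 in mesenchymal-like, 2199 and 1996 in macrophage-like and 1735 and 1662 in endothelial-like cells. Of the 28 list tests 16 passed by fry but 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05). Scaled by library size alone the splits were 765 to 7105, 1240 to 5427, 1291 to 4410 and 1128 to 3316, with the median gene shifted by −0.444, −0.493, −0.339 and −0.196, so directions hold relative to the median gene. Clusters with much hepatocyte RNA took more of mesenchymal-, macrophage- and endothelial-like cells in regression than in fibrosis (below). Without them 2771 mesenchymal and 1947 macrophage genes were called in place of 4834 and 4195, the TGF beta and PDGF list and the contractile list were not called, and Acta2 was at −0.99. In cells of 1000 to 3000 UMIs these lists and that of proteases were not called, nor the contractile list with predicted doublets kept. The largest cluster in regression was 41 among endothelial-like cells (68.6%, with 3.5% in cluster 6), 24 among macrophage-like (47.4%), 18 among mesenchymal-like (36.2%) and 33 among hepatocyte-like cells (37.9%).

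**Figure D3:**
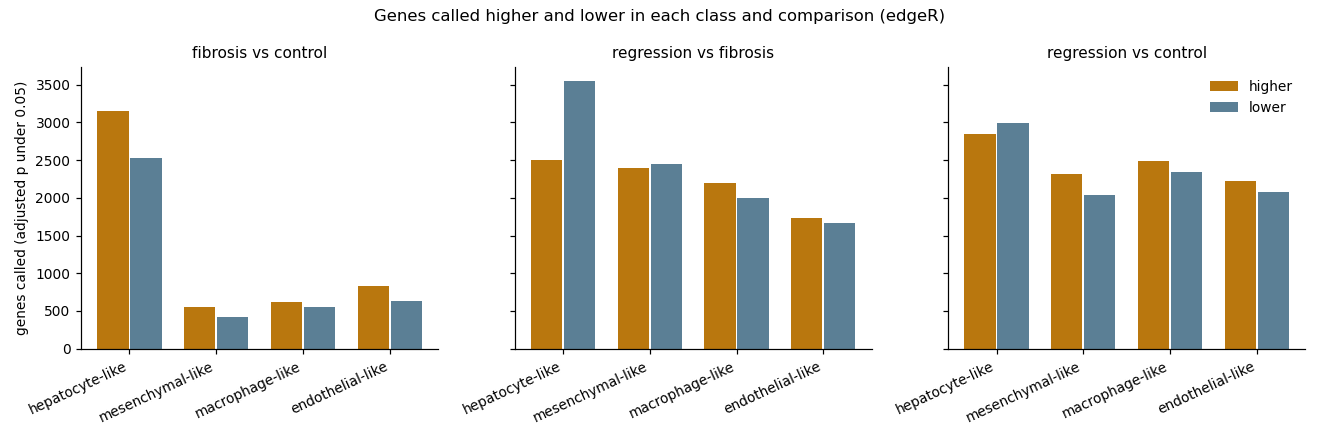
Bars give the number of genes called higher and lower by edgeR in each class (horizontal axis) and comparison (panel), at an adjusted p under 0.05. In mesenchymal-like cells 967 genes were called between fibrosis and control.

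The comparison of regression with control asks what still differed after recovery. Of the pericentral markers of hepatocyte-like cells, Glul was at 243 ± 24.9 against 166 ± 21.8 CPM (0.55 ± 0.30, adjusted p = 0.153) and Cyp2e1 was at 3560 ± 305 against 1990 ± 657 CPM (0.83 ± 0.39, adjusted p = 0.103). Both were called higher in the fit of only these groups (Glul 0.54, adjusted p = 0.0199, Cyp2e1 0.83, 0.0319), and Cyp2e1 with DESeq2 (0.86, 0.0378). NRF2 targets stayed high: 12 of 14 rose relative to control (13 over the list alone, fry adjusted p = 0.00141, adjusted p = 0.36 with an estimated correlation), Gstm3 from 19.9 ± 11.8 to 247 ± 79.0 CPM and the quinone reductase Nqo1 from 3.26 ± 0.492 to 12.7 ± 3.04 CPM. Of 20 cell cycle genes 13 were higher, also over the list alone (fry adjusted p = 0.0233, adjusted p = 0.842 with an estimated correlation). That call ended without control library 1 or regression library 1 and in the fit of only these groups. Mki67 rose by 3.10 ± 0.67 and Plk1 by 1.5 ± 0.26. Of 12 fetal and ductal genes 4 were higher, also over the list alone (fry adjusted p = 0.0269, adjusted p = 0.842 with an estimated correlation), Afp by 2.25 ± 0.41, and the call ended without control library 1 or 2 or regression library 1 or 2, in the same fit, and with that class-mean filter. Susd4 stayed 19.1-fold lower (1.62 ± 0.685 against 31.3 ± 5.24 CPM).

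Other lists of hepatocyte-like cells did not pass in regression against control. Of 16 pericentral genes 4 were higher and 1 lower (3 and 1 over the list alone, fry adjusted p = 0.237), and of 15 acute phase genes 0 and 7 (0 and 9 over the list alone, 0.213). Of 14 periportal genes 3 and 1 differed (0.237), of 15 bile acid genes 3 and 0 (0.110), of 13 p53 targets 3 and 2 (0.173) and of 9 male-biased genes 3 and 0 (0.0615), with the same counts over the list alone. Single members differed: the ammonium transporter Rhbg was 2.85-fold higher, Mup20 4.86-fold higher (5810 ± 229 against 1200 ± 328 CPM), Slc22a3 4.39-fold lower and Phlda3 3.33-fold higher. Cdkn1a (0.04 ± 0.36, adjusted p = 0.941, turning sign without 1 library), Cyp7a1 (−0.35 ± 0.38, 0.486) and Sox9 (−0.24 ± 0.32, 0.552, but 0.15 without control library 3 and −0.57 with adjusted p = 0.024 without control library 2) did not pass. The largest rises were of the clock gene Dbp (4.02 ± 0.74), Gstm3 (3.63 ± 0.43) and the cytochrome P450 gene Cyp2a4 (23.2 ± 8.97 to 223 ± 66.6 CPM). Among the largest falls were Mup12 (−3.33 ± 0.63) and Prtn3, a protease of myeloid cells (−6.83 ± 2.27, adjusted p = 0.0438, 25.9 ± 43.5 CPM in control). The latter call rested on control library 3 (−1.86, adjusted p = 0.119 without it) and also ended without regression library 1, 2 or 3.

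Col1a1 of mesenchymal-like cells was near control in regression (977 ± 190 against 779 ± 102 CPM, 0.33 ± 0.40, adjusted p = 0.540, −0.04 with library size scaling), while other matrix genes still differed. The proteoglycan gene Lum was 2.14-fold higher (264 ± 29.6 against 123 ± 10.8 CPM), Mfap4 4.56-fold higher, and Col5a1 2.12-fold lower (540 ± 144 against 1140 ± 163 CPM). Of 25 matrix genes 4 were higher and 3 lower, also over the list alone (fry adjusted p = 0.732). Timp3 (282 ± 16.3 against 66.4 ± 25.9 CPM, 2.10 ± 0.29) and Plat (1.93 ± 0.33) stayed high. Of 13 proteases and inhibitors 3 were higher, also over the list alone (fry adjusted p = 0.049, adjusted p = 0.845 with an estimated correlation). The list's call ended without any 1 library, with library size scaling (0.621), in the fit of only these groups, with the stricter cell filter and with that class-mean filter. Of 15 quiescent stellate genes 6 were lower, also over the list alone (fry adjusted p = 0.0615), among them the collectin gene Colec10 (360 ± 49.6 against 889 ± 168 CPM) and Vipr1 (354 ± 120 CPM, −1.44 ± 0.35). Lrat (−0.69 ± 0.28, adjusted p = 0.0643), Acta2 (1.89 ± 0.96, 0.156) and Timp1 (1.24 ± 1.05, 0.371) did not pass. Lists that did not pass were the contractile list (2 of 9 lower, also over the list alone, fry adjusted p = 0.476), the TGF beta and PDGF list (2 of 16 higher and 2 lower, 2 and 1 over the list alone, 0.732) and immediate early genes (1 of 16 higher and 2 lower, also over the list alone, 0.110).

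The largest falls of mesenchymal-like cells against control were those of the glutamate receptor gene Grin2b (31.5 ± 10.7 to 2.83 ± 1.18 CPM), the protocadherin gene Pcdh15 (26.7 ± 6.56 to 2.67 ± 3.52 CPM) and Spon2 (399 ± 124 to 53.3 ± 10.3 CPM, −2.90 ± 0.28). With the stricter cell filter Col5a1 (0.13) and Vipr1 (0.04) of this comparison turned direction and were not called. The rises were led by hepatocyte genes, Gstm3 (5.43 ± 0.39), Cyp2a4 (4.93 ± 0.75) and Gsta2 (a ratio of 54.6 from 1 UMI in control, 9.7 to 2170, with a fitted 5.48 that was 8.65 without control library 2), at 42.7%, 40.7% and 43.1% of their hepatocyte level.

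Macrophage-like cells kept scar-associated genes after recovery. Gpnmb was at 701 ± 163 against 1.28 ± 0.229 CPM (a ratio of 550 from 3 UMIs in control, 188 to 2670), Trem2 at 97.0 ± 14.7 against 33.8 ± 2.97 CPM (1.52 ± 0.20) and Cd63 8.59-fold higher. Of 17 listed genes 10 were higher, also over the list alone (fry adjusted p = 0.00482, adjusted p = 0.655 with an estimated correlation). Atp6v0d2 was at least 17.1-fold higher (no UMI in control, 21.7 ± 8.18 CPM in regression, against 3 UMIs over the group, adjusted p = 0.105 with the stricter cell filter). Clec4f (−0.07 ± 0.24, adjusted p = 0.820), Timd4 (−0.19 ± 0.31, 0.657) and Spp1 (2.30 ± 1.27, 0.191) did not pass. Of 13 Kupffer genes 3 were higher and 1, Nr1h3 (565 ± 51.3 against 1110 ± 152 CPM), lower, also over the list alone (fry adjusted p = 0.735, with a median of −0.03 and a mean of 0.11). Saa1 and Saa2, acute phase genes of hepatocytes at 25.1% and 26.3% of their hepatocyte level, fell by 6.03 and 7.17 (adjusted p = 0.0341 and 0.0311). Both calls rested on control library 3: without it the values were −2.70 and −3.54 (adjusted p = 0.0547 and 0.0524), and they ended without regression library 1, 2 or 3 too, each kept in 13 of 20 other settings.

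Endothelial-like cells kept capillary genes and gained sinusoidal ones. Cd34 was at 63.3 ± 12.9 against 13.4 ± 1.30 CPM (2.25 ± 0.20, adjusted p = 3.04e-06), Ly6a at 410 ± 110 against 63.3 ± 9.86 CPM, Ednrb 17-fold higher (4.09 ± 0.46) and Plvap 2.02-fold higher. Of 15 capillary and vascular genes 8 were higher, also over the list alone (fry adjusted p = 0.00233, adjusted p = 0.36 with an estimated correlation, and 0.122 with Scrublet's automatic thresholds). Of 18 sinusoidal genes 8 were higher and 3 lower (10 and 3 over the list alone, fry adjusted p = 0.0337, adjusted p = 0.845 with an estimated correlation). The call ended without control library 1, 2 or 3 or regression library 1 or 2, with library size scaling (0.139), with automatic thresholds and in the fit of only these groups. Oit3 was 1.98-fold and Lyve1 1.91-fold higher, while Stab2 (2410 ± 42.5 against 4130 ± 478 CPM, −0.78 ± 0.15) and Stab1 (−0.61 ± 0.15) were lower. Of 17 immediate early genes 6 were higher, also over the list alone (fry adjusted p = 0.011, adjusted p = 0.698 with an estimated correlation). This call ended without regression library 2 and with the stricter cell filter. Jun was at 0.79 ± 0.13. Gstm3 (3.55 ± 0.45) and the glucuronosyl transferase gene Ugt1a9 (3.53 ± 0.42), at 25.2% and 25.1% of their hepatocyte level, were among the largest rises. The largest falls, of Saa1 (−7.29 ± 2.11, adjusted p = 0.0354) and Saa2 (−7.97 ± 2.33, 0.0369), rested on control library 3 (−3.81 and −4.05, adjusted p = 0.0678 and 0.0739 without it) and ended without any 1 regression library as well, as did Mup12 (−2.65 ± 0.74, and −1.5 without control library 3).

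By edgeR, 2844 genes were higher and 2996 lower in hepatocyte-like cells, 2309 and 2032 in mesenchymal-like, 2494 and 2347 in macrophage-like and 2220 and 2077 in endothelial-like cells. By fry 9 of 28 list tests passed, but 4 without control library 1, regression library 1 or regression library 2, 5 without control library 2, and 0 by camera with an estimated correlation (2 at an unadjusted p under 0.05). Scaled by library size alone the last 3 splits were 1379 to 3900, 1673 to 3795 and 1808 to 2795, with the median gene shifted by −0.408, −0.291 and −0.113. Without the clusters high in hepatocyte RNA 2121 mesenchymal and 2935 macrophage genes were called.

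Whether the genes changed by TAA moved back during recovery was asked from genes called in both steps with opposite signs. In hepatocyte-like cells 2907 of 12756 genes did so, 1936 that rose with TAA and fell in recovery and 971 that fell and rose, which is 61.4% of the genes that rose and 38.4% of those that fell. Mesenchymal-like cells had 499 (356 and 143, or 65.2% and 34.0%), macrophage-like cells 396 (193 and 203, or 30.9% and 36.5%) and endothelial-like cells 511 (272 and 239, or 32.7% and 37.5%). If the calls of the 2 steps were independent, 1374.2, 210.1, 228 and 227.4 genes would be shared this way. The fibrosis libraries stand in both steps and their noise alone gives opposite signs. In 20 simulated sets without group effects at most 1 gene was called in both directions in any class, but without effects few genes can pass, so how many of the calls this noise adds among changed genes was not measured. The covariance of the changes was −0.96, −0.32, −0.10 and −0.143 in the 4 classes, against −0.04, −0.043, −0.033 and −0.03 in the simulated sets. The correlation was −0.725, −0.412, −0.185 and −0.359, against −0.507, −0.433, −0.41 and −0.487, beyond the simulated mean only in hepatocyte-like cells. Shared libraries alone set that mean, so values short of it decide nothing. Genes called with the same sign in both steps numbered 378, 62, 220 and 154. With library size scaling the sides were 4511 and 205, 477 and 82, 353 and 138, and 520 and 165 in the 4 classes. With the class-mean filter they were 515 and 419, 231 and 107, 101 and 145, and 173 and 149. The mesenchymal sides were 330 and 357 without clusters high in hepatocyte RNA and 143 and 243 in cells of 1000 to 3000 UMIs.

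Summed over all cells of a library, which mixes class shares with changes within classes, 3626 genes were higher and 3940 lower of 13932 in fibrosis against control, 2792 and 3004 in regression against fibrosis, and 3536 and 3649 in regression against control (edgeR). Scaled by library size alone these splits were 9125 to 573, 880 to 7209 and 4844 to 2011, with the median gene shifted by 0.664, −0.446 and 0.218. On the mm10 genome, some of the genes named lie at chromosome 1, 153899944 to 153909723 (Glul, ENSMUSG00000026473) and chromosome 11, 94936224 to 94953042 (Col1a1, ENSMUSG00000001506).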

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

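Planned settings were fixed before the data were examined, and the others, listed with the alternatives above, were chosen after they were seen. Of 4338 named-gene values under other settings 4040 were kept, 261 weaker, 7 stronger and 30 reversed, and with 1 library left out 1809 of 2016 were kept, 198 weaker, 2 stronger and 7 reversed. The cause was not tested except where a setting removes libraries. Replicate numbers did not pair libraries (same-numbered r from −0.245 to 0.160), so the block is given here only. With it 15, 15 and 11 lists were called in the 3 comparisons, without the contractile and quiescent stellate lists of fibrosis against control, and Prtn3, Saa1 and Saa2 were not called in regression against control. In fibrosis against control it called 5623, 809, 1114 and 1276 genes in the 4 classes.

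With DESeq2 and with RLE factors Cyp7a1 in regression against fibrosis was 0.02 and Sox9 0.01, and in the fit of only the 2 groups compared 0.04 and 0.02. That fit called 5 lists in regression against control in place of 9. With the replicate block Cdkn1a was −0.01 in regression against control. With camera 0, 0 and 0 lists were called. Of the other lists that did not pass, library size scaling called endothelial immediate early genes in fibrosis against control, clock, cytokine, interferon and hepatocyte and macrophage immediate early genes (all down) in regression against fibrosis, and male-biased genes (up) and contractile, quiescent stellate and mesenchymal and macrophage immediate early genes (down) in regression against control.

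Scaled by library size only, in fibrosis against control Cyp7a1 was 0.11 and Sox9 0.27, in regression against control Col1a1 was −0.04, in regression against fibrosis Plvap was −0.02, and 4716 hepatocyte genes were called in both directions.

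With genes under 0.25 of the highest class mean left out, hepatocyte-like cells had 2080, 2834 and 2998 genes called in the 3 comparisons, by construction from fewer genes, mesenchymal-like cells 627 in fibrosis against control, and genes called in both directions were 934 (hepatocyte-like), 246 (macrophage-like) and 322 (endothelial-like).

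With predicted doublets kept, mesenchymal-like cells had 2145 genes called in regression against fibrosis and 1436 in regression against control. Scrublet's automatic thresholds removed doublets unequally between groups. With them fibrosis against control had 1662 mesenchymal, 3194 macrophage and 2735 endothelial genes, Lrat was −0.12 there and Plvap −0.04 in regression against fibrosis.

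The stricter cell filter left 7 libraries for mesenchymal-like cells (control 1 and 2 out) and 8 for endothelial-like cells (control 1 out). It called 85 mesenchymal, 388 macrophage and 338 endothelial genes in fibrosis against control and 16, 1927 and 777 in regression against control, and 72, 250 and 182 in both directions. In mesenchymal-like cells of fibrosis against control Col5a3 was 1.48 and Slco1a1 3.29, and in regression against control Col1a1 was −0.09, Col5a1 0.13, Col5a3 1.32, Des 0.43, Klf2 0.46, Lrat 0.40, Ltbp2 −0.03, Timp1 −1.22, Tpm2 0.63 and Vipr1 0.04.

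Without clusters high in hepatocyte RNA, regression against fibrosis had 2771 mesenchymal and 1947 macrophage genes and regression against control 2121 and 2935. Mmp19 of mesenchymal-like cells was −0.09 and Hspb1 of macrophage-like cells −0.07 in regression against fibrosis, and Clec4f was 0.01 in regression against control.

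In cells of 1000 to 3000 UMIs, mesenchymal-like cells had 1543 genes called in regression against fibrosis and 734 in regression against control, macrophage-like cells 3151 in regression against control, and endothelial-like cells 911, 1455 and 1762 in the 3 comparisons and 301 in both directions. In regression against fibrosis Gpnmb was 0.16 and Cd34 0.03.

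Of 12 classes 11 differed in share, 7 among cells not hepatocyte-like, and 6 (without fibrosis 2) to 10 (without control 2) with 1 library left out. With 1 library left out, fibrosis against control had 524 (without fibrosis 1) to 841 mesenchymal genes, with 573, 544 and 626 without control 2, control 3 and fibrosis 3. It had 644 (without fibrosis 1) to 1204 macrophage genes, with 709 and 706 without control 2 and fibrosis 3, 816 (without control 2) to 1547 endothelial genes, with 978 and 973 without control 3 and fibrosis 3, and 215 (without control 1) to 349 cholangiocyte genes. Genes called in both directions were 281 (without fibrosis 1) to 475 in mesenchymal-like cells, with 326 without control 3, and 210 (without fibrosis 1) to 445 in macrophage-like cells, with 243 without fibrosis 3. Lists called in regression against control were 4 (without control 1, regression 1 or regression 2) to 7, and 5 without control 2. Sox9 ranged from −0.52 to 0.19 in fibrosis against control (0.19 without control 3), −0.10 to 0.07 in regression against fibrosis (0.07 without regression 3) and −0.57 to 0.15 in regression against control (0.15 without control 3). Cyp7a1 ranged from −0.24 to 0.31 in regression against fibrosis (0.15 without fibrosis 3, 0.31 without regression 1) and Cdkn1a from −0.49 to 0.30 in regression against control (−0.19 without control 3, −0.49 without regression 1).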

Other observations

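Cholangiocyte-like cells were compared after their numbers were seen (82 to 124 per control library, 338 to 598 in fibrosis, 127 to 202 in regression). In fibrosis against control Arnt2, a bHLH-PAS factor, was at 71.5 ± 11.6 CPM with no UMI in control, at least 11.8-fold higher against 3 UMIs over the group, as were Greb1, an oestrogen-responsive gene (40.6 ± 10.0 CPM, at least 6.87-fold), and Sbspon, of the matrix (29.0 ± 3.27 CPM, at least 4.85-fold). C2cd4b fell by 5.06 (SE 0.87, adjusted p = 0.00051, or 0.122 without control library 1). In regression against fibrosis the mitotic gene Cenpf was 108-fold lower (19.1 to 4270), and Ckap2 and Pimreg, also of dividing cells, at least 32.7- and 30.2-fold lower. The test called 150 genes higher and 280 lower of 10987 in fibrosis against control (215 in all without control library 1), 2194 and 2234 in regression against fibrosis and 1142 and 872 in regression against control (edgeR). By library size alone the last 2 splits were 1310 to 4413 and 718 to 1685.

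Several gene lists of hepatocyte-like cells did not pass in fibrosis against control or in regression against fibrosis. With library size scaling, in fibrosis against control clock genes (fry adjusted p = 0.00932), PPAR alpha targets (0.0315), cholesterol synthesis (0.0224) and immediate early genes (0.0224) passed. The clock gene Dbp rose from 5.53 ± 4.21 to 70.5 ± 46.6 CPM in fibrosis (3.68 ± 0.72). Of 16 clock genes 4 rose and 1 fell, also over the list alone (fry adjusted p = 0.203, then 0.338 with 3 up, 0 over the list alone, and 0.0615 in regression against control with 7 up and 3 down, 7 and 4 over the list alone). As clock genes went both ways against control, fry's test of direction cannot decide whether the clock differed. PPAR alpha targets, of fatty acid use, had 3 of 13 up (1 over the list alone, 0.204), then 7 up and 1 down, also over the list alone (0.121), and passed in regression against control with 7 up, also over the list alone (fry adjusted p = 0.0337, adjusted p = 0.845 with an estimated correlation), which ended without any 1 of the 6 libraries. Its member Acadm, of fatty acid oxidation, was at 94.3 ± 28.7 CPM in control and 260 ± 6.11 CPM in regression (1.47 ± 0.21). Cholesterol synthesis had 3 of 14 up, also over the list alone (0.118, but 0.00233 without control library 3), 1 up and 2 down (0 and 0 over the list alone, 0.787) and 3 up (2 over the list alone, 0.213), with the squalene synthase gene Fdft1 up by 1.16 ± 0.27 in fibrosis. Acute phase genes had 4 of 15 up in regression against fibrosis (3 over the list alone, 0.397). Immediate early genes had 4 of 18 up and 4 down, also over the list alone (0.251), 0 and 5 (0 and 3 over the list alone, 0.0810) and 4 and 2, also over the list alone (0.476).

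In macrophage-like cells, H2-Aa, which presents antigen to T cells, rose from 366 ± 128 to 1210 ± 159 CPM in regression against fibrosis (1.73 ± 0.31), at 19.5% of its highest level in another class. Of 9 antigen presentation genes 0 rose and 2 fell in fibrosis against control (1 and 2 over the list alone, fry adjusted p = 0.797), 2 rose in regression against fibrosis (4 and 1 over the list alone, 0.219) and 5 rose and 1 fell against control, also over the list alone (0.194). The cytokine gene Il1a fell from 196 ± 14.4 to 114 ± 24.9 CPM in fibrosis (adjusted p = 0.152 with the stricter cell filter), with 2 of 14 cytokine genes down (also over the list alone, 0.584), then 1 down (also over the list alone, 0.317), and 1 up and 3 down against control (0 and 3 over the list alone, 0.213). Of 14 interferon genes 0 changed in fibrosis against control by edgeR (0 over the list alone, 0.435), and 4 fell in regression against fibrosis, also over the list alone (0.185), among them the antiviral gene Oas1a (−0.76 ± 0.16), with 1 up and 3 down against control, also over the list alone (0.556). Immediate early genes had 1 of 18 up and 2 down in regression against fibrosis (1 and 1 over the list alone, 0.656) and 3 up and 4 down against control, also over the list alone (0.556).

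Of the tests of patterns below, the ratio of doublet scores and the 2 tests of shared changes were set before their values were seen, and those of free RNA and of the top genes after. Changes of regression against fibrosis were shared by the mesenchymal-, macrophage- and endothelial-like classes, with a median Spearman rho of 0.801 between classes over 6497 genes, against 0.494 for fibrosis against control. Among 870 genes low in hepatocyte-like cells and without clusters high in hepatocyte RNA it was 0.565, and in cells of 1000 to 3000 UMIs 0.683, so neither hepatocyte RNA nor depth per cell accounts for all of it. A difference between groups of libraries in handling or batch cannot be told from recovery, since each library belongs to 1 group.

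Clusters with much hepatocyte RNA took 1.5 ± 1.36%, 17.0 ± 5.49% and 29.9 ± 5.50% of mesenchymal-like cells in control, fibrosis and regression, 5.14 ± 2.36%, 13.8 ± 2.97% and 47.3 ± 3.27% of macrophage-like cells and 0.41 ± 0.36%, 5.27 ± 2.39% and 15.4 ± 2.02% of endothelial-like cells (SD, n = 3). The ratio of their doublet scores to those of other cells of the class was 3.47 in mesenchymal-like and 2.919 in endothelial-like cells, past the 1.5 set for doublets, but 1.123 in macrophage-like cells, which leaves undetected doublets open. If free RNA were the source, their Alb UMIs per cell would be under 1.5 times those of other cells of the class in every regression library, and a ratio of at least 2 in every library would exclude it. The medians of this ratio over the regression libraries were 4.138 in mesenchymal-like and 10.045 in endothelial-like cells, which excludes free RNA as the whole source there in regression, and 1.347 in macrophage-like cells, which leaves it open. In fibrosis the mesenchymal-like ratios were 0.769, 1.125 and 1.118, which leaves it open there too. Without these clusters Alb in regression lay at 25.9 ± 0.77%, 21.4 ± 2.29% and 17.0 ± 1.78% of the hepatocyte level.

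Scaling by library size called 6595 hepatocyte genes higher and 597 lower in fibrosis. With the 50 top genes taken out of the library size the sides were 5612 and 810, a ratio of 6.93, so those genes were not the whole cause, and they may account for part of it. Their share of UMIs was 36.17 to 41.3% in control, 33.52 to 35.2% in fibrosis and 38.26 to 38.71% in regression.

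Over all other splits of the 6 libraries of a comparison (10 with the real one), edgeR called 0 genes in any class compared or the whole-library sum, and fry 0 lists. The real split stood alone (value 1) in all 21 tests, too few splits for a share under 0.05. Genes called in both directions numbered 2907, 499, 396 and 511 in the real grouping and 0 in the others of 40 assignments. All others mix the groups, which widens the spread within them, so their 0 tests neither chance nor reversal.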
